A study of Mus musculus with 4 samples.

How the data were processed

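The data are single-cell RNA counts from F4/80-positive peritoneal cells of 4 mouse samples, 1 in each of 4 groups. Per the labels' protocols, the peritoneal cavity was washed with 10 mL of cold buffer, cells passed a 100 µm strainer and were stained for F4/80, viable F4/80-positive cells were sorted, and libraries were made with a 10x Genomics 3' kit, which counts the 3' ends of transcripts by molecular identifiers (UMIs). Per the labels and the series' design text, the high-fat diet held 21% fat and 0.15% cholesterol and ran for 20 weeks from an age of 4 weeks, a normal diet was given again a week before the first immunization, and at week 21 the mice received 3 mg of the antibody in 200 µL or buffer alone. Male sex is stated for the Apoe-deficient mice of the diet groups only.

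The authors deposited 1 matrix of whole-number UMI counts for 31253 genes and 26811 barcodes, made with Cell Ranger 5.0.1 per the file headers. The submitters' processing notes name CASAVA 1.8, Cell Ranger, Seurat and the mm10 build, without a role for each. The counting settings, the cell calling and the gene annotation are not given in the sources used here. Whether introns were counted or free RNA removed is likewise not given in the sources used here. The barcode suffixes 1 to 4 were taken as 4 libraries. As no label or header ties a suffix to a sample, the planned differences between groups were not computed, and libraries were never assigned to a group from their order or values. Where a gene lies comes from GENCODE M21 on GRCm38, the assembly also called mm10, with positions counted from 1.

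Barcodes were kept with at least 500 detected genes and at most 10% mitochondrial UMIs. The gene limit removed 707, 247, 847 and 924 barcodes from libraries 1 to 4, and the mitochondrial limit a further 1936, 495, 296 and 495. Doublets were called per library with Scrublet as run by scanpy 1.11.5 at default settings. It marked 95 of 5547, 10 of 6518, 7 of 5607 and 2 of 6414 tested barcodes, and in libraries 2, 3 and 4, at 0.153, 0.125 and 0.0312%, it has not worked, so doublets remain there. Of the marked barcodes that passed the other filters, 57, 10, 7 and 2 were removed. Kept cells numbered 3554, 6013, 5304 and 5917, with median depths of 8128, 11511, 13306 and 12406 UMIs and medians of 2714.5, 3000, 3098 and 2903 detected genes.

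All kept cells were clustered together, without integration, after scaling to 10000 UMIs per cell and log transformation, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. The 14 clusters were named from 13 fixed lists of cell type markers; a name needed at least 3 markers detected in 10% of a cluster's cells and a mean log2 ratio of the markers to the other clusters above 0.5, and among such names the one with most markers among the 10 leading genes was taken. That scoring rule was set after the matrix was read. Macrophage-like means the 7 clusters named as large peritoneal or as small peritoneal or monocyte-derived macrophage, 16927 cells in all. Leading genes of these clusters were, by number, Lyve1 and Cbr2 (0), Retnla and Clec4a2 (1), Ear2 and Cd209a (5), Cxcl1 and Cxcl2 (8), Ttc39c and Cxcl13 (9), Apoe and Cdkn2a (10) and Chil3 and Iigp1 (12). Cluster 5 also scored for dendritic cell genes, and cluster 8 was led by inflammatory genes. In cluster 3, B cell-like, haemoglobin genes were among the leading genes, each with a UMI in 0.426% of its cells or fewer. A cluster of 175 cells with markers of both macrophages and lymphocytes, at a median of 19020 UMIs, was left unnamed and out of every class; it held 10, 74, 53 and 38 cells of libraries 1 to 4. Levels are summed UMIs per 1000000 (CPM).

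For the Lyve1 share and the comparison of Lyve1-positive with Lyve1-negative cells, each cell was thinned at random to 3000 UMIs and shallower cells were left out. UMIs were summed over positive and over negative cells within a library, and log2 ratios of CPM were formed with a prior count of 0.5, leaving Lyve1 out of the totals. A gene was past the rule of size with at least 20 CPM in the higher of both sets and a log2 ratio of at least 1 in size and of 1 sign in every library. Cells are not replicates, so no p-value was computed. Genes named are the 12 with the largest and the 12 with the smallest median log2 ratio among those past the rule, leaving out gene models without a symbol, and members of the fixed lists at 20 CPM in either set; Apoe, Lyve1 and the Col6a genes are given for each library. Positive cells were few in libraries 2, 3 and 4 (113, 89 and 121), so ratios of genes near 20 CPM rest on about 10 UMIs or fewer there. For each of 17 fixed gene lists and for the marker lists, the median ratio in a library was placed among 10000 random lists of the same size drawn from 20 bins of expression, as a description of that library; a percentile needed 3 members. The lists hold 337 symbols, of which 334 were used: Clec7a and Mx1 are not in the matrix under these symbols, and Aldoa was left out because its symbol stands for more than 1 gene. The 91 genes that share a symbol with another gene were kept apart by their identifiers. The groups, lists, markers, filters, rule of size and most alternatives were fixed before the data were examined.

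The comparison was tested on simulated counts drawn from the real means and library sizes, with 50 genes changed at each of 4 fold sizes among 4520 genes at 20 CPM. The rule of size called 54% of genes at a log2 ratio of 1.25, 38% at -1.25, 100% at 2.5 and 88% at -2.5, and 0 of the 4320 unchanged genes at 20 CPM. The simulated counts were Poisson draws of summed UMIs, without variation between cells or clusters. That 0 is therefore no rate of false calls in the real data. The recovery first asked for at the larger folds was not reached at -2.5, and the requirement was lowered after that result. The rule therefore misses many changes close to its limit, and some at -2.5 as well. Why they were missed was not tested.

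Alternatives changed 1 choice at a time: 20% mitochondrial UMIs, 1000 detected genes, doublets kept, Leiden resolution 1.0, thinning to 2000 UMIs or none, at least 2 Lyve1 UMIs, only the largest macrophage-like cluster of each library, 50 or 5 CPM, each library left out in turn, and list means or members at 5 CPM. Chosen after seeing the data were leaving out the cluster that also scores for dendritic cell genes, ratios centred on the median gene, and a second random draw. Alternatives that changed the set of cells or the thinning depth also drew the thinning anew. Their results are therefore not separated from the effect of a fresh draw. Left out were differences between groups, for want of a map, and reads, which were not analysed here. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.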

Results

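Single-cell transcriptomes were recorded from peritoneal cells carrying F4/80, a macrophage surface protein encoded by Adgre1, sorted from mice aged 24 weeks. The labels describe 4 groups with 1 sample each: C57BL/6 mice on a normal diet, Apoe-deficient mice on a normal diet, Apoe-deficient mice after 20 weeks of a high-fat diet, and Apoe-deficient mice after the same diet that received 3 mg of a monoclonal antibody against collagen VI. Apoe encodes apolipoprotein E, a carrier of cholesterol, and mice without it develop atherosclerosis. The series title concerns macrophages that express Lyve1, the gene of a hyaluronan receptor, after the collagen VI antibody. The matrix held 26811 cell barcodes and 31253 genes. Barcodes carried 1 of 4 suffixes, taken here as libraries, with 6254, 6765, 6454 and 7338 barcodes in libraries 1 to 4. Total UMI counts were 40321459, 74067998, 73429015 and 78083803. Neither the labels nor the file headers tie a suffix to a sample, so no comparison between genotypes, diets or treatments was made, and every value below belongs to a library of unknown group. With 1 library per group there are no replicates and no test across libraries. Intervals in parentheses are exact 95% intervals (Clopper-Pearson for shares and ratios, Poisson for UMI sums) and cover counting error only.

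Apoe, the deleted gene of 3 of the 4 groups, was detected in macrophage-like cells of all 4 libraries, at levels that spanned orders of magnitude. Its level was 30.2 CPM (UMIs per 1000000; 27.7 to 32.7) in library 1, 847 CPM (839 to 854) in library 2, 710 CPM (703 to 716) in library 3 and 30159 CPM (30117 to 30200.0) in library 4. In B cell-like cells it was 8.20, 60.4, 74.1 and 1243 CPM in libraries 1 to 4, and in T cell-like cells 2.97, 88.8, 201 and 5852 CPM. Because no library is tied to a genotype, these values check no label, and where the deleted part of the gene lies is not given in the sources used here, so a 3' tag need not report the deletion. Apoe lies on chromosome 7 from 19696109 to 19699188 on the minus strand of GRCm38, and Lyve1 on the same chromosome from 110850607 to 110863239, also on the minus strand; both are protein-coding genes. Lyve1 stood at 445 CPM (435 to 454) in macrophage-like cells of library 1 and at 16.2 (15.2 to 17.2), 17.0 (15.9 to 18.0) and 18.1 CPM (17.1 to 19.2) in those of libraries 2, 3 and 4. In B cell-like cells it was 7.79, 0.521, 0.893 and 0.415 CPM, and in T cell-like cells 6.94, 1.23, 1.61 and 5.56 CPM. The genes of the collagen VI chains were close to the detection limit in macrophage-like cells. Col6a1 had 31, 1, 1 and 1 UMIs in libraries 1 to 4, Col6a2 had 12 UMIs in library 1 and 0 in the others, and Col6a3 had 1 UMI in library 4 and 0 in the others; counted as 3 UMIs, a value of 0 allows up to 0.158, 0.0507, 0.0480 and 0.0441 CPM. The summed level of the mesothelial and stromal cell markers in the same cells was 87.8 CPM in library 1 and 0.220, 0.192 and 0.191 CPM in libraries 2, 3 and 4, with Dcn, the gene of the matrix proteoglycan decorin, at 62.9, 0.135, 0.160 and 0.103 CPM. Dcn lay almost wholly in cluster 5, where it was at 199 CPM but had a UMI in 0.978% of cells. Its level in library 1 thus rests on few cells and is not that of macrophage-like cells in general.

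**Figure D1:**
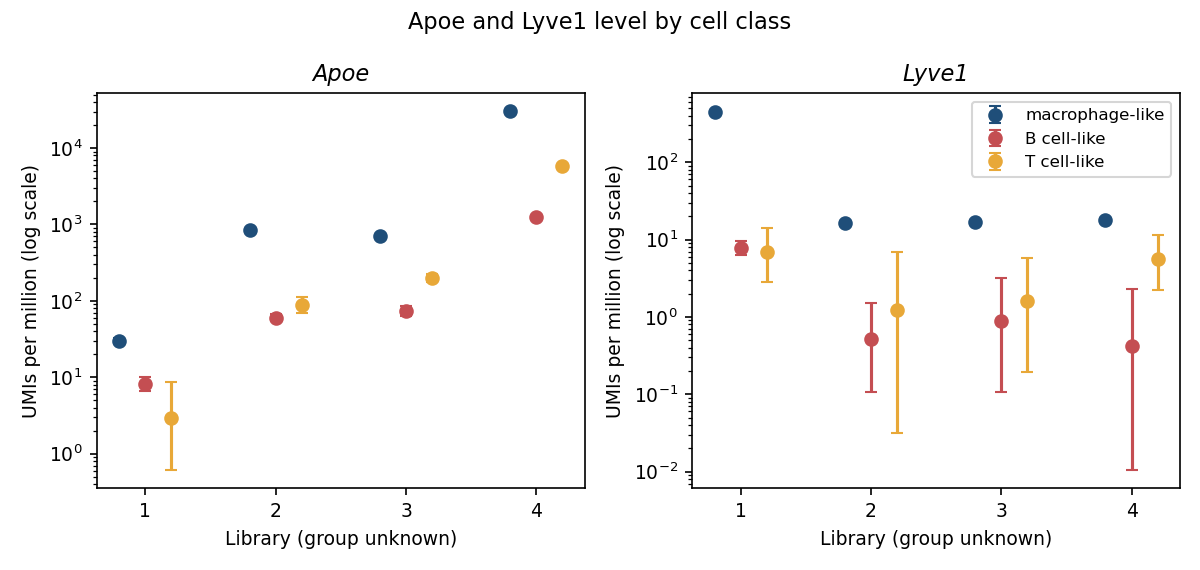
Apoe (left) and Lyve1 (right) in CPM on a log scale, by library and cell class, with exact Poisson 95% intervals. Apoe in macrophage-like cells runs from 30.2 CPM in library 1 to 30159 CPM in library 4, and Lyve1 is 445 CPM in library 1 and 16.2 to 18.1 CPM in the others.

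Macrophage-like cells were the main class in each library. They made up 66.3% (64.7 to 67.8) of 3554 kept cells in library 1, 81.6% (80.6 to 82.6) of 6013 in library 2, 84.1% (83.1 to 85.0) of 5304 in library 3 and 88.0% (87.1 to 88.8) of 5917 in library 4. Lymphocytes remained beside them despite the sort: B cell-like cells were 27.6, 11.1, 7.09 and 5.85% of kept cells, and T cell-like cells 4.56, 2.13, 3.98 and 3.13%. Proliferating cell-like cells, named from cell cycle genes such as Mki67 and Top2a, were 0.478, 3.61, 3.54 and 2.32%. Mast cell-like cells numbered 27, 3, 8 and 4, and neutrophil-like cells 1, 16, 9 and 1. Different clusters held the macrophage-like cells of the libraries: cluster 0 held 2112 of the 2356 in library 1, cluster 12 held 3027 and cluster 1 held 1345 of the 4906 in library 2, clusters 9 and 10 held 2203 and 1610 of the 4459 in library 3, and cluster 10 held 4041 of the 5206 in library 4. A cluster drawn mostly from 1 library, such as cluster 0, may be that library and not a cell type, so the large and small peritoneal macrophage clusters were joined and their sizes are not compared between libraries. The same holds for the B cell-like cells, of which 956 of 981 in library 1 lay in a cluster of their own. Filters removed 43.2% of the barcodes of library 1 and 11.1, 17.8 and 19.4% of those of libraries 2, 3 and 4, and median depth was 7558.5, 11817.5, 13688 and 12703.5 UMIs per macrophage-like cell.

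**Figure D2:**
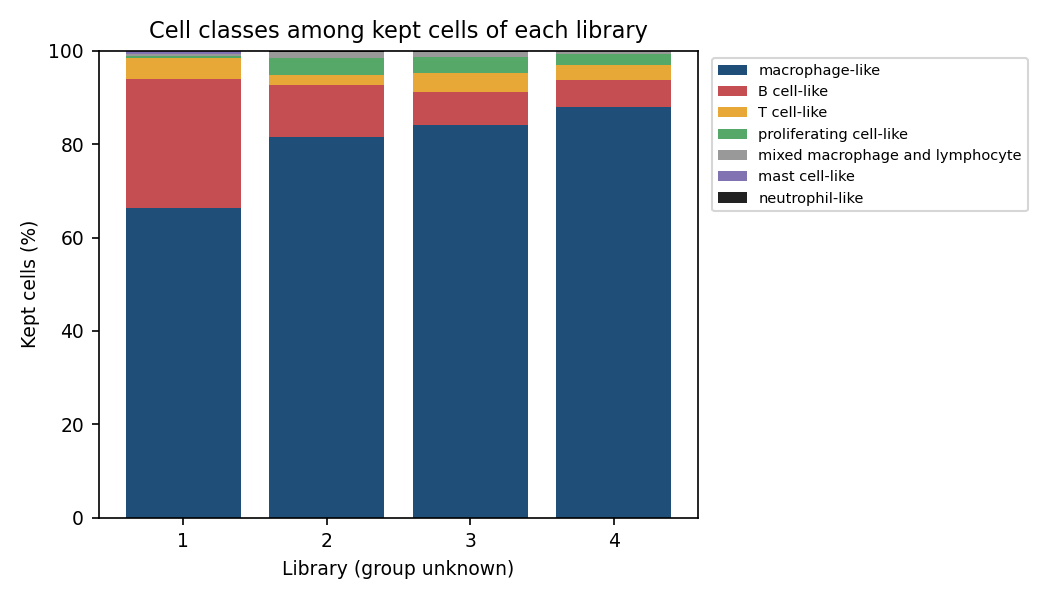
Share of kept cells (%) in each cell class, stacked for libraries 1 to 4 of unknown group. The macrophage-like share runs from 66.3% in library 1 to 88.0% in library 4, and the B cell-like share from 27.6% to 5.85%.

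The share of macrophage-like cells with a Lyve1 UMI addressed the gene named in the title. After every cell was thinned to 3000 UMIs, it was 37.0% (34.9 to 39.1; 777 of 2099 cells) in library 1, 2.38% (1.97 to 2.86; 113 of 4744) in library 2, 2.01% (1.62 to 2.47; 89 of 4421) in library 3 and 2.35% (1.95 to 2.80; 121 of 5154) in library 4. Thinning left out 257, 162, 38 and 52 shallower cells. Without thinning, the shares were 43.8, 4.02, 3.63 and 4.67%. B cell-like cells, which should lack Lyve1, gave the background: 2.69% (1.77 to 3.92; 26 of 965) in library 1, 0.156% (up to 0.865; 1 of 642) in library 2, 0.311% (up to 1.72; 1 of 322) in library 3 and 0.313% (up to 1.73; 1 of 320) in library 4. In T cell-like cells the thinned share was 2.04% (3 of 147 cells), 0.820% (1 of 122), 0 of 181, with an upper limit of 2.02%, and 0.629% (1 of 159). Median depth was 10704, 7177, 5057 and 6481 UMIs in B cell-like cells and 5201, 5255.5, 4404 and 5443 UMIs in T cell-like cells. The macrophage-like interval lay above the B cell-like one in libraries 1, 2 and 4 and overlapped it in library 3, and it lay above the T cell-like one in library 1 alone. Within macrophage-like cells, 40.7% of the thinned cells of cluster 0 in library 1 had a Lyve1 UMI (762 of 1873), against 5.33% (69 of 1295), 8.45% (29 of 343) and 4.24% (36 of 850) of cluster 1 in libraries 2, 3 and 4. Cluster 0 held few thinned cells of the other libraries. In library 2, 9 of 25 had a Lyve1 UMI, 36% (18.0 to 57.5). In library 3 it held 5 positive and 3 negative cells, and in library 4 it held 1 and 4. Lyve1 is a leading gene of cluster 0, so its shares partly follow from how the cluster was formed.

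**Figure D3:**
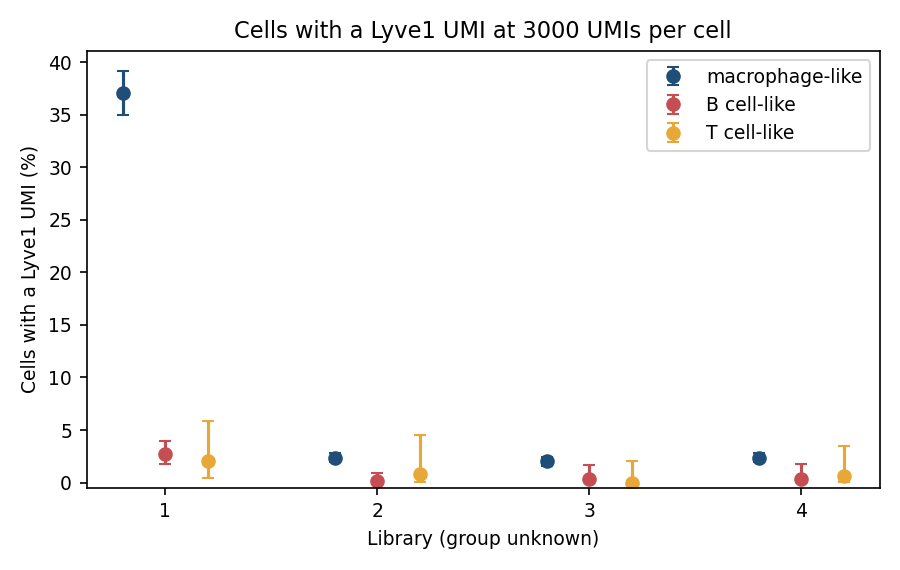
Percent of cells with a Lyve1 UMI after thinning to 3000 UMIs per cell, by library and cell class, with exact binomial 95% intervals. The macrophage-like share is 37.0% in library 1 and 2.01 to 2.38% in libraries 2 to 4; the B cell-like and T cell-like points show the background.

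Macrophage-like cells with a Lyve1 UMI were compared with those without inside each library, which needs no map to groups. In all 4 libraries the Lyve1-positive cells had higher levels of Cbr2, a carbonyl reductase, Folr2, the folate receptor beta, Tns1, a focal adhesion protein, Cd163, the haptoglobin-haemoglobin scavenger receptor, Stab1, a scavenger receptor also called stabilin 1, Lgals1, the beta-galactoside-binding lectin galectin 1, Fcna, a ficolin of the lectin pathway of complement, and Psd3. They had lower levels of Slpi, a secreted inhibitor of serine proteases, and Napsa, an aspartic protease. These 8 genes were the higher and these 2 the lower ones past the rule of size, which asked for 20 CPM in the higher cell set and a log2 ratio of at least 1 in size in every library; 4823 genes reached 20 CPM. The count depends on the draw: a second random thinning gave 5 higher and 1 lower genes, of which 4 and 1 are among these, and thinning to 2000 UMIs gave 3 and 0. Folr2 passed the rule in 17 of 17 alternatives and Cbr2 in 16, but Fcna in 7 and Psd3 in 5. The minimum of 5 CPM and leaving out 1 library only relax the rule, so no gene could fail in those 5 settings. Psd3 passed in no other. Cbr2 had log2 ratios of 1.79 (1.59 to 1.98), 3.22 (2.71 to 3.68), 3.77 (3.07 to 4.37) and 3.59 (2.83 to 4.25) in libraries 1 to 4, and Folr2 1.31 (1.20 to 1.42), 2.69 (2.45 to 2.91), 3.99 (3.66 to 4.31) and 3.53 (3.16 to 3.88). For Tns1 the ratios were 1.34, 2.39, 2.23 and 2.84, for Stab1 1.53, 2.74, 1.34 and 1.82, for Lgals1 1.02, 1.75, 1.59 and 1.45, and for Fcna 1.17, 1.88, 1.41 and 1.04. Cd163 was at 2.09, 2.03, 2.44 and 2.77, the last 3 from 13, 8 and 12 UMIs in Lyve1-positive cells. Psd3 was at 1.05, 1.08, 1.39 and 1.08, with intervals that include 0 in libraries 2 and 4. Slpi was at -1.32 (-1.42 to -1.21), -1.23 (-1.32 to -1.13), -1.35 (-1.43 to -1.27) and -1.40 (-1.47 to -1.33). Napsa was at -1.85, -2.12, -2.69 and -1.54, the last 3 from 6, 1 and 4 UMIs in Lyve1-positive cells. The median ratio of all 4823 genes was 0.05, 0.19, 0.16 and 0.14, and with ratios centred on it 5 genes were higher and 2 lower. Library 1 limited the count, which without it was 20 higher and 4 lower, and inside the largest macrophage-like cluster of each library 3 genes were higher and 0 lower. The cells of that cluster were thinned anew, so the drop is not separated from a fresh draw. Positive cells there numbered 26, 14 and 87 in libraries 2, 3 and 4, so the order and signs of ratios inside it rest on few cells. Inside that cluster the median ratio of Cbr2 was 1.69, below those of Tns1 (2.64), Folr2 (2.32) and Stab1 (2.06), while Lgals1 at 0.98, Psd3 at 0.38 and Napsa at -0.43 had no common sign in the 4 libraries. Napsa also was at -0.43, without a common sign, when the cluster that scores for dendritic cell genes was left out, so its lower level is not shown apart from those cells. The remaining cells were thinned anew there, and with the second random draw alone the median of Napsa was -1.70. The median of Slpi was -0.80 without thinning.

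**Figure D4:**
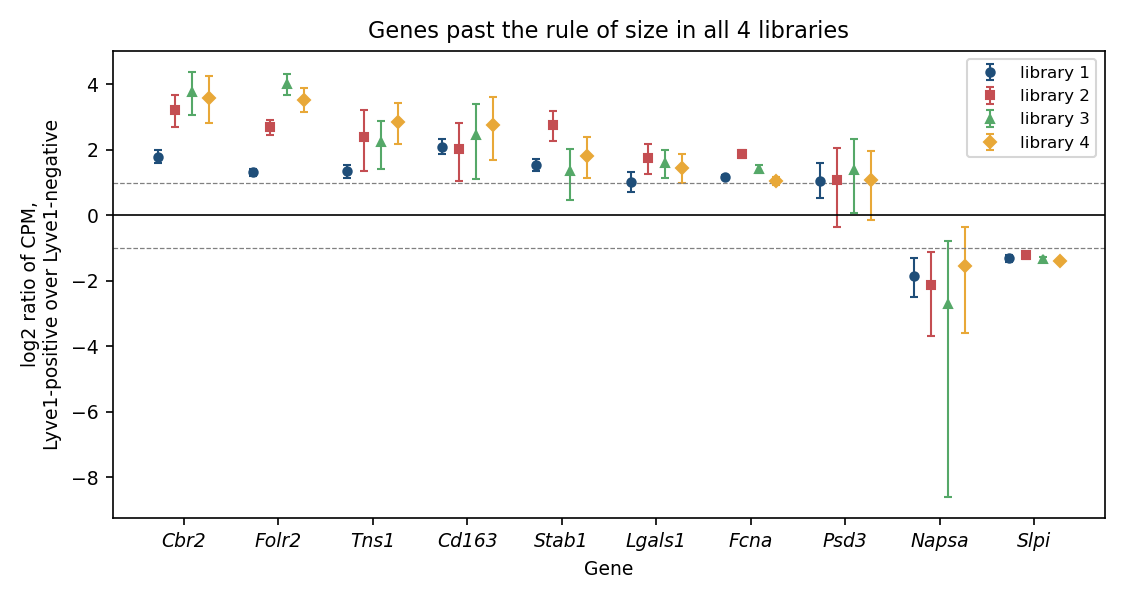
Log2 ratio of CPM in Lyve1-positive over Lyve1-negative macrophage-like cells for the 10 genes past the rule of size, by library, with exact intervals of the ratio; dashed lines mark a log2 ratio of 1 in either direction. Among these 10 genes and over all macrophage-like cells, Cbr2 and Folr2 have the largest medians over libraries, 3.40 and 3.11, and Slpi lies between -1.23 and -1.40.

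The list of resident Lyve1 macrophage genes stood highest among the fixed lists. Over all 4823 genes, 1277 were higher and 319 lower in Lyve1-positive cells of all 4 libraries, so an excess of higher over lower members is general, and counts such as 2 of 9 or 5 of 14 do not set a list apart. Of its 8 members at 20 CPM in every library, 7 were higher in Lyve1-positive cells of all 4 libraries and 4 passed the rule of size: Folr2, Cbr2, Cd163 and Fcna. Mrc1, the mannose receptor, had ratios of 0.67, 1.53, 3.24 and 1.88, F13a1, coagulation factor XIII subunit A, 0.76, 1.13, 1.54 and 1.52, and Pf4, the chemokine platelet factor 4, 0.75, 1.55, 0.46 and 0.60. Timd4, a phosphatidylserine receptor of resident macrophages, had -0.46, 0.18, -0.09 and 0.23. Gas6 had 2.15, 3.51, 4.87 and 3.86, with a median of 3.69. It missed the rule because it was at 19.3 CPM in positive cells of library 4, and it had 8, 10 and 7 UMIs in positive cells of libraries 2, 3 and 4. The list's median was 1.17, 1.88, 2.44 and 1.70, at percentile 100 of 10000 random lists matched on expression in each library. Of 10 alternative activation genes, 6 were higher and 1 lower in all 4 libraries, and only Cd163 passed the rule. Retnla, a secreted protein of alternatively activated macrophages, had 0.12 in library 1 and 2.35, 2.44 and 2.09 in libraries 2, 3 and 4, while Chil3, a chitinase-like protein, had -0.31, -1.39, -1.59 and -1.03 and Arg1, arginase 1, had 0.23, -0.12, 0.49 and 0.81. The median of that list was 0.23, 0.30, 0.60 and 0.58, at percentiles 99.2, 89.4, 99.95 and 99.98. Retnla leads cluster 1, which held 61.1, 32.6 and 29.8% of positive but 26.5, 7.25 and 16.2% of negative cells of libraries 2, 3 and 4, so its ratios there are not separated from that difference in clusters. Of 11 scavenger receptor genes, 6 were higher in all 4 libraries and Stab1 and Cd163 passed the rule; Marco had -0.90 in library 1 and 0.67, 1.09 and 1.75 in the others. The list's percentiles were 95.7, 99.6, 99.0 and 99.9. Mrc1 and Cd163 belong to all 3 of these lists.

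Genes of cholesterol efflux and targets of the liver X receptor had small positive ratios. Of 12 members at 20 CPM, 7 were higher in all 4 libraries and 0 passed the rule. Abca1, a cholesterol exporter, had 0.56, 0.63, 0.70 and 0.54, Abcg1, a partner exporter, 0.61, 1.03, 0.60 and 0.24, and Mylip, a ligase that lowers the LDL receptor, 0.92, 0.59, 0.29 and 0.59. Apoe, a member too, had 0.08, -0.56, -0.31 and -0.11. The list's median was 0.19, 0.45, 0.39 and 0.35, at percentiles 98.4, 98.2, 96.3 and 97.0.

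Class II antigen presentation genes and markers of large peritoneal macrophages lay lower in Lyve1-positive cells. Of 7 MHC class II genes at 20 CPM, 5 were lower in all 4 libraries (Cd74, H2-Aa, H2-Ab1, H2-Eb1 and H2-DMb1) and 0 passed the rule. Cd74, the invariant chain, had -1.01, -0.80, -0.33 and -0.07. The list's median was -1.01, -0.69, -0.25 and -0.08, at percentiles 0, 0, 5.15 and 23.9, so in libraries 3 and 4 it lay within the range of random lists. Positive and negative cells lay in different clusters: in library 1, cluster 5, with class II genes at 45567 CPM against 6599 CPM in cluster 0, held 14.1% of negative and 1.29% of positive cells, and in library 2, cluster 12, at 21842 CPM against 8508 CPM in cluster 1, held 62.7% and 26.5%. List medians inside a single cluster were not computed, so the lower class II level is not separated from this difference in clusters. Of 15 large peritoneal macrophage markers, 8 were lower in all 4 libraries, among them Prg4, Alox15, Selp and Ltbp1, 0 passed the rule, and the percentiles were 0, 0.0600, 0.0100 and 0.820. These ratios too are not separated from clusters: the large peritoneal cluster 9 held 19.1% of positive and 50.4% of negative cells of library 3, and cluster 10 held 62.0% and 78.1% of those of library 4. Of 9 small peritoneal or monocyte-derived macrophage markers, 4 were higher (Folr2, Mrc1, Retnla and Clec10a) and 5 lower in all 4 libraries, with percentiles 0, 80.4, 23.4 and 16.6; its lower members are Ccr2 and 4 genes shared with the class II list. Of 4 classical monocyte markers, Chil3 and Hp were lower and F13a1 higher in all 4 libraries, with percentiles 0.215, 0, 0.0150 and 0.0800.

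None of the remaining lists had a median outside the central 95% of random lists in every library. Medians of the efferocytosis, complement, iron and haem, lipid-laden, collagen VI and matrix, and fatty acid oxidation lists were positive in each library. So was the median ratio of all genes. Lipid-laden macrophage genes were split, with 5 of 13 higher and 3 lower in all 4 libraries: Ctsb, a lysosomal protease, had 0.46, 0.65, 0.58 and 0.70 and Trem2, a lipid-sensing receptor, 0.47, 0.84, 0.59 and 1.18, while Fabp4, a fatty acid-binding protein, had -0.65, -0.46, -0.94 and -0.71 and Cd9, a tetraspanin, -0.89, -0.75, -0.70 and -0.58; the percentiles were 69.4, 91.6, 51.2 and 84.5. Of 14 efferocytosis genes 5 were higher and 0 lower in all 4 libraries (percentiles 96.7, 63.4, 87.7 and 95.3), and Stab1 alone passed the rule. Of 11 complement genes 4 were higher and C4b was lower (90.1, 50.1, 91.0 and 99.2), with C5ar1, a receptor of the fragment C5a, at 0.38, 0.55, 0.91 and 0.68. Of 7 iron and haem genes 3 were higher (99.9, 40.5, 86.5 and 62.4), Cd163 among them past the rule. Of 6 Fc receptor genes 2 were higher and 1 lower (42.6, 30.7, 26.1 and 76.7), with Fcgrt, the neonatal Fc receptor, at 0.77, 0.86, 0.97 and 0.74. Of 3 collagen VI and matrix genes Timp2, a metalloproteinase inhibitor, was higher (87.9, 95.4, 89.8 and 80.3). Of 5 interferon response genes 2 were higher (61.5, 5.67, 90.7 and 53.3). Of 9 fatty acid oxidation genes 2 were higher and 1 lower (29.3, 46.5, 16.8 and 12.5), and of 11 glycolysis genes 3 were higher (1.71, 28.9, 85.7 and 66.4). Of 10 early response and dissociation stress genes 2 were higher and Socs3 was lower (3.85, 32.0, 0.880 and 21.2). None of the 4 classical activation genes had the same sign in all libraries (26.8, 41.6, 56.3 and 79.7). Of 2 cholesterol synthesis genes Insig1 was higher, and the list had 7 and 10 members at 20 CPM in libraries 1 and 2 (0.340 and 3.31) but 2 in each of the others, too few for a percentile. B cell markers had percentiles of 68.6 and 91.1 in libraries 1 and 2 and too few members elsewhere. Dendritic cell, neutrophil, mast cell and mesothelial or stromal markers had at most 2 members at 20 CPM in any library, and T cell, NK cell, eosinophil, red cell and proliferating cell markers had 0.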

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

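The tests in this part were chosen only after the results were seen.

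Lyve1 UMIs were also present in cells that no comparison used, with a lower limit above the share in B cell-like cells of the same library. Among barcodes removed for their mitochondrial share, 35.0% (31.4 to 38.7; 238 of 680 thinned cells) in library 1, 6.70% (3.62 to 11.2; 13 of 194) in library 2, 3.76% (1.53 to 7.60; 7 of 186) in library 3 and 4.46% (2.33 to 7.66; 12 of 269) in library 4 had a Lyve1 UMI, and 1256, 301, 110 and 226 of these barcodes were too shallow to count. These barcodes were not assigned to cell classes, and the B cell-like shares beside them were 2.69, 0.156, 0.311 and 0.313%. Among proliferating cell-like cells the share was 2.30% (0.752 to 5.29; 5 of 217) in library 2, 3.19% (1.18 to 6.82; 6 of 188) in library 3 and 2.92% (0.801 to 7.31; 4 of 137) in library 4, intervals that overlap those of B cell-like cells. In the cluster with markers of both macrophages and lymphocytes it was 4 of 74 cells, 5.41% (1.49 to 13.3), in library 2. There it was 1 of 8, 1 of 53 and 0 of 38 in libraries 1, 3 and 4, with lower limits below the B cell-like shares.

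The Lyve1 share of macrophage-like cells was far higher in library 1 than in libraries 2, 3 and 4. A difference in depth as the whole cause is argued against by the thinned share, 37.0% in library 1, whose lower limit of 34.9% lies above the highest upper limit of the others, 2.86%. Free RNA is argued against by the B cell-like cells of library 1, of which 2.69% had a Lyve1 UMI at the same thinned depth. Sex or handling of the animals of that library stays open and cannot be told apart from other causes, because over 50% of kept cells had an Xist UMI in 1 library, and it is the same library. Genotype, diet and antibody, the differences the design names, also stay open and were not tested, since no library is tied to a group. Male sex is stated for the Apoe-deficient mice of the diet groups, while 89.4% of kept cells of library 1 had an Xist UMI. The Lyve1 level alone thus does not mark library 1 as the antibody group.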

How the results depend on the processing

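Leaving out the cluster that also scores for dendritic cell genes, centring the ratios and the second random draw were chosen after seeing the data, as were the bounds behind the counts of lists below; the other alternatives were planned. Of the values and counts that answer a comparison, 59 stayed (shares within their interval, depths between their quartiles, counts within 1.5 times) and 39 moved; of the other values 99 stayed and 35 moved. The list of early response and dissociation stress genes, close to 0, changed sign with list means. The cause was not tested unless stated. Without filters the median depth of library 1 was 4808 UMIs, since shallow barcodes come back. The macrophage-like share of library 1 was 71.0% with up to 20% mitochondrial UMIs, and without the dendritic-scoring cluster the shares were 60.4, 79.8, 82.0 and 86.6% in libraries 1 to 4, by construction. The Lyve1 share follows depth by construction: it was 32.7% in library 1, 1.93% in library 2 and 1.93% in library 4 at 2000 UMIs, and 43.8, 4.02, 3.63 and 4.67% without thinning. With at least 2 Lyve1 UMIs it was 27.1, 1.14, 1.04 and 1.07%, and without the dendritic-scoring cluster 40.6% in library 1. In each of these settings the share of library 1 was the highest. Genes higher in Lyve1-positive cells numbered 5 with up to 20% mitochondrial UMIs, 3 at 2000 UMIs, 4 without thinning, 16 with at least 2 Lyve1 UMIs, 3 in the largest cluster, 4 without the dendritic-scoring cluster, 5 with the second draw, 5 at 50 CPM, 13 at 5 CPM and 5 with centred ratios, and 8 to 20 with a library left out. Genes lower numbered 4 at resolution 1.0, 0 at 2000 UMIs, 1 without thinning, 0 in the largest cluster, 1 with the second draw, 1 at 50 CPM, 4 at 5 CPM and 2 to 4 with a library left out. A fresh draw alone thus moved the count of higher genes from 8 to 5, with 4 shared. Settings that changed the cells or the thinning depth carried a fresh draw as well. Of 17 alternatives, Tns1 passed the rule in 15, Stab1 and Slpi in 14, Cd163 and Napsa in 11, and Lgals1 in 10. Each of these numbers includes the settings at 5 CPM and with a library left out, which only relax the rule and which no gene could fail. Lists above the central 95% of random lists in all 4 libraries were 1 by medians and 3 by means, and lists below it 0, or 1 with members at 5 CPM. The alternatives set for differences between groups (filters, resolution, scaling, minimum, thinning, largest cluster) were not run, as no library is tied to a group. No paired analysis was possible because each group has 1 sample and no library is tied to a sample. The small number of Lyve1-positive cells, 113, 89 and 121, limits the ratios in libraries 2, 3 and 4.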

Other observations

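In this part all tests but the one on molecules of library 1 were chosen only after the results were seen, as were the genes singled out.

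Some genes of resident and of recruited peritoneal macrophages, picked after their values were seen, differed between macrophage-like cells of the 4 libraries. Gata6, the transcription factor of large peritoneal macrophages, was at 48.9 CPM (45.8 to 52.2), 63.4 (61.4 to 65.4), 129 (127 to 132) and 136 CPM (133 to 139) in libraries 1 to 4, and Timd4 at 57.1, 80.4, 255 and 325 CPM. Cxcl13, a B cell chemokine, was at 513, 302, 3436 and 2047 CPM, and Fabp4 at 178, 329, 1465 and 1193 CPM. Ccr2, the chemokine receptor of recruited monocytes, was at 309 CPM (301 to 317), 143 (140 to 146), 29.2 (27.8 to 30.5) and 40.4 CPM (38.9 to 41.9). The summed class II genes were at 11755, 17270, 4979 and 7675 CPM. For these genes the values of libraries 1 and 2 lay on one side and those of libraries 3 and 4 on the other, and the macrophage-like cells of these libraries lay mostly in different clusters. In library 1 the class II genes were at 45567 CPM in cluster 5 but at 6599 CPM in cluster 0, below the 7675 CPM of library 4. Ccr2 was at 1330 CPM in cluster 5 and 56.8 CPM in all other kept cells. The class II and Ccr2 differences are thus not separated from cluster 5, which also scored for dendritic cell genes. The fixed list of large peritoneal macrophage markers summed to 21725, 22699, 33307 and 23091 CPM, with libraries 2 and 4 close together and Saa3 as the largest part; 9 of its 15 members were highest in library 3, 5 in library 4 and 1 in library 1.

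Genes of alternative activation were summed to 13820, 5298, 2982 and 2270 CPM in libraries 1 to 4. Retnla was at 10597, 1087, 1048 and 815 CPM and Mrc1 at 428, 71.1, 22.1 and 24.5 CPM, while Chil3 was at 1137, 2695, 568 and 128 CPM and Arg1 at 373, 528, 313 and 276 CPM. Saa3, an acute-phase protein, was abundant in each library, at 15152, 15570, 18851 and 10408 CPM. Picked after their values were seen and from no fixed list, 4 targets of the glucocorticoid receptor were all lowest in library 4. Fkbp5 was at 112, 54.0, 111 and 10.4 CPM in macrophage-like cells, Tsc22d3 at 363, 305, 313 and 170.2 CPM, Klf9 at 243, 260.1, 268 and 124 CPM and Per1 at 30.6, 33.1, 35.0 and 13.3 CPM. In B cell-like cells they were at 50.9, 51.4, 63.4 and 17.4 CPM for Fkbp5, 660.1, 529, 667 and 508 CPM for Tsc22d3, 18.0, 10.2, 13.8 and 7.88 CPM for Klf9. Per1 in these cells was at 12.1, 10.3 and 7.47 CPM in libraries 1, 3 and 4 and between the first and second of these in library 2. The 7 genes near Apoe on chromosome 7 that were looked at had no common direction in macrophage-like cells. Apoc4 was at 542, 105, 34.5 and 29.2 CPM and Apoc1 at 172, 19.5, 19.2 and 15.8 CPM, while Apoc2 was at 1.11, 11.7, 5.80 and 6.87 CPM and Tomm40 at 20.2, 31.4, 29.4 and 28.0 CPM. Bcam was at 73.6, 110.2, 76.5 and 75.7 CPM, Clptm1 at 51.3, 46.8, 39.5 and 36.4 CPM, and Nectin2 at 4.32, 2.25, 1.44 and 1.45 CPM. In B cell-like cells Nectin2 was at 58.4 CPM (54.3 to 62.9) in library 1 and 0.415 CPM in library 4, with 0 UMIs in libraries 2 and 3, which at 3 counts allows up to 0.521 and 1.34 CPM.

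Without library 1, 12 more genes were past the rule of size as higher in Lyve1-positive cells and Chil3 and Prtn3 as lower. Among them, Retnla had log2 ratios of 2.35, 2.44 and 2.09 in libraries 2, 3 and 4 against 0.12 in library 1, Maf, a transcription factor, 1.48, 1.75 and 1.53 against 0.92, and the chemokine gene Ccl6 1.33, 1.30 and 1.29 against 0.43. Retnla and Ccl6 are leading genes of cluster 1, which holds a larger part of the positive than of the negative cells in libraries 2, 3 and 4 and under 0.5% of both in library 1.

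Xist, the RNA of the inactive X chromosome, was seen in 89.4% of kept cells of library 1 and in 0.0499, 0.0189 and 0.0676% of those of libraries 2, 3 and 4, while UMIs of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were in 0.0849, 78.3, 77.3 and 76.2% of macrophage-like cells of libraries 1 to 4. In libraries 2, 3 and 4 they were in 74.1, 54.0 and 60.4% of B cell-like and 60.9, 55.9 and 58.9% of T cell-like cells. Free RNA as the source is argued against by the lowest Xist share over macrophage-like, B cell-like and T cell-like cells of library 1, 86.0%. A mixture of male and female cells is argued against by the Y-linked share of all kept cells of library 1, 0.0563% with an upper limit of 0.203%, where a mixture was set to need 5%. Library 1 held Xist almost without Y-linked UMIs, and libraries 2, 3 and 4 held the reverse. A difference in the sex of the animals would give this. Sex was not tested by other values, since Xist and the Y-linked genes are the pattern itself. The labels give the sex of some groups only, and no library was tied to a group from these values.

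Lyve1-positive cells shared Cbr2, Folr2, Tns1 and Cd163 in all 4 libraries, although library 1 held most Lyve1 UMIs. Molecules of library 1 assigned to the other libraries are argued against as the source by Xist: counted without thinning, the 197, 162 and 243 macrophage-like cells with a Lyve1 UMI in libraries 2, 3 and 4 held 0 Xist UMIs, 0% of the 575, 637 and 743 that such molecules would bring, with upper limits of 0.641, 0.579 and 0.496%. That cells with Lyve1 lie in other clusters than cells without stays open as a part of the pattern. Within the largest cluster of each library the median ratio of the 8 genes exceeded that of all genes by 1.12, 1.49, 0.99 and 1.67, a median of 1.30, against 1.27, 1.97, 1.71 and 2.12 over all macrophage-like cells. The 8 genes were chosen for their ratios in these same cells, so the values over all macrophage-like cells are high by selection. Cells of the largest cluster were also thinned anew, so both sets of values rest on different draws. The largest cluster of library 3 had 14 Lyve1-positive cells in this draw and 17 in the main one. All genes here means those at 20 CPM in either cell set of that library. With 14 positive cells very few UMIs reach that limit. The median ratio of all genes was 0.57 in library 3, against 0.05, 0.33 and 0.16 in libraries 1, 2 and 4. The value of 0.99 is thus not separated from this choice of genes. Neither bound set for that test was met in every library.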
